A study of Danio rerio with 6 samples.

How the data were processed

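Poly(A) RNA from zebrafish trunks was sequenced in 3 control and 3 qkia/c loss of function libraries. Per the labels, oligo(dT) selection started from 0.7 µg of RNA, the TruSeq libraries did not keep the strand of the transcript, and the 6 libraries shared 2 lanes with 50 bp reads. Without strand, reads of a gene and of an overlapping antisense gene are not told apart. Embryos were injected with 0.6 pmol of morpholino and sorted into groups by their morphology, per the labels. Groups and replicate numbers were taken from the sample titles.

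The deposited values are a normalized signal: per gene or per exon, a read count divided by 1 size factor per library, as the deposited values themselves show. The submitters' processing notes name the genome build Zv9 and the tools Bowtie 0.12.9, STAR 2.4.0j, SAMtools, HTSeq 0.5.3 and DESeq 1.8.3, without saying which did what. How reads shared between near-identical genes were counted is not given in the sources used here. In every library 100% of the values were whole multiples of the value of 1 read, within a tolerance of 0.001 of a read, so whole reads could be recovered. The size factors recovered ranged from 0.897 to 1.13 for genes and from 0.875 to 1.22 for exons.

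The recovered gene tables hold 38804265 to 44799398 reads per library, and those of exons hold 42722193 to 49332381. The labels give a mean of 27459238 reads per sample with a spread of 1611623, which is lower, and the reason is not given in the sources used here. The 10 most abundant genes took 11.3% to 13.2% of the reads. Between 1335 and 1813 genes were at 0 in a library. Control replicate 1 had 34167 exons at 0, fewer than any other library, and the highest number was 47524.

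Gene names came from a table that pairs Ensembl gene IDs with symbols, in which 18555 of 24789 IDs (74.9%) had one. Many zebrafish genes carry a human name there, in capitals and shared by co-orthologues, and such genes are given with their ID. No coordinates of build Zv9 were used here, so none are given.

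The main test was limma 3.58.1 in R 4.3.3, with eBayes and an intensity trend, on log2 of the deposited value plus a pseudocount of 1. Genes with a value of at least 10 in at least 3 of the 6 libraries were tested. Fold changes are on this log2(value + 1) scale, which understates the change of genes with low values. All p-values are 2-sided and adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. Means are given with the SD over 3 libraries, and the p-values measure the spread between these libraries. Gene lists were tested with limma's camera, with a preset inter-gene correlation of 0.01 and with an estimated one, and with fry, for lists with at least 3 tested members and adjusted over the 29 lists.

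The 29 lists held 821 members, of which 704 were matched to a gene ID. Of those, 227 were matched through the human name after a final a or b or number was dropped, so that a list can hold both copies of a duplicated gene. This matching was fixed before the values were looked at. The rule for named genes took the targeted genes, their paralogue and the tropomyosins, then the 12 largest increases and decreases among genes with a symbol, a mean of at least 50, no overlap between the groups and an adjusted p under 0.05. It also took up to 4 members per list with the smallest adjusted p. Genes named beyond it, as where 5 or fewer members of a list moved in a direction, were chosen after their values were seen, as was pth1b. Lists of Hox, hatching gland, mitochondrially encoded and immediate early genes were also chosen then. The values of 1 list and of a member of another are not reported here.

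The planned test of exon usage, an exon against the other exons of its gene, needs a pairing of exons with genes and was not run. In its place limma tested each exon with a mean of at least 10, a choice made after the data were seen. Exons carry no gene names here, and 2 that rose and 2 that fell are given.

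On the recovered reads, edgeR 4.0.16 (quasi-likelihood test, TMM) and DESeq2 1.42.0 were run as alternatives. Other alternatives changed the pseudocount to 0.5 or 5, the filter, the scaling, the trend, the replicate number as a block, and left out each library in turn. Reads were loaded with Python 3.11.15 and pandas 2.3.3.

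The tests were tried on simulated data with known changes. In simulated gene libraries with 18938 genes, limma recovered 80% of 1.5-fold changes, 98.7% of 2-fold changes and 100% of 4-fold changes, and 10 of 198 calls were false. In simulated exon libraries with 26057 exons, it recovered 43.1%, 88.2% and 100%, and 5 of 160 calls were false. In the simulated gene libraries 0 of the 29 lists were called by camera. The simulated genes were drawn independently and the changed genes at random. This 0 therefore does not show how camera behaves where members of a list vary together.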

Results

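Messenger RNA was sequenced from the trunks of zebrafish (Danio rerio) embryos collected 24 to 26 h after fertilization, after the head and the yolk had been cut away. The 3 control libraries came from embryos with at least 1 intact copy of qkia that had received a control morpholino. The 3 loss of function libraries came from siblings homozygous for a qkia mutation that had received a morpholino against qkic. Morpholinos are antisense oligonucleotides that block the translation or splicing of a chosen transcript. Quaking proteins bind RNA and act on its splicing, stability and translation, and the series set out to find target genes of qkia and qkic. Its design gave a single comparison, loss of function against control, in which genotype and morpholino changed together in every library.

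Each library had a table of normalized read counts for 24789 genes and another for 253038 exons. The gene tables corresponded to 44084480, 40613426 and 40131452 reads in control replicates 1, 2 and 3, and to 44799398, 44273390 and 38804265 reads in loss of function replicates 1, 2 and 3. The exon tables held between 42722193 and 49332381 reads. The first principal component carried 60.5% of the variance and separated the groups. Pearson's r across genes, which are not independent replicates, was 0.992 to 0.995 between libraries of the same group and 0.981 to 0.986 between libraries of different groups. The chi-square per degree of freedom was 8.4 to 15 between controls and 2.18 to 2.54 between loss of function libraries, where sampling of independent reads alone gives about 1. The counts exceed the reads in the labels and library preparation adds spread, so these values do not show separate biological samples. Controls differed more from each other, while the limma fit used 1 variance per gene for both groups. All 6 were kept as separate samples because the series describes them as biological triplicates. It does not say how many embryos each held.

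The mutated gene, qkia (ENSDARG00000097478), fell from a normalized read count of 67.5 ± 12.6 in controls to 5.42 ± 1.86 in loss of function trunks (SD, n = 3 in each group), which was 10.9-fold lower. Its log2 change was -3.45 (SE 0.30) with a limma adjusted p = 1.93e-07. The libraries held 70, 83 and 58 qkia reads in controls against 6, 7 and 3 in loss of function. No gene in the tables is named qkic, qki2 or qkib, and 2 further genes carry the human name QKI without a way to tell which of them the morpholino targeted. The more abundant, ENSDARG00000010018, fell 1.92-fold, from 637 ± 41.1 to 331 ± 21.4, with a log2 change of -0.94 (SE 0.08, limma adjusted p = 1.42e-07). The other, ENSDARG00000002026, had 38.4 ± 3.52 and 41.9 ± 6.81, a log2 change of 0.12 (95% interval -0.32 to 0.55) that did not pass the test (limma adjusted p = 0.684). A morpholino need not change the level of the transcript it binds, so these values do not measure its effect.

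The changes reached far beyond the quaking genes. Of 18917 genes tested, 4143 were higher and 3792 were lower in loss of function trunks at a limma adjusted p under 0.05, together 41.9%. Most of these changes were small. At least 2-fold changes were found in 245 genes in the upward and 309 in the downward direction, and at least 4-fold changes in 44 and 19. The 2 groups did not overlap for 9864 genes (52.1%, where chance gives 10%), and 7680 of those passed the test. On whole reads recovered from the values, edgeR called 4024 genes higher and 3922 lower, sharing 7780 of the 7935 limma calls in the same direction. DESeq2 called 3605 and 3141.

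Tropomyosin genes, which encode the filament that runs along actin and gates myosin binding, moved in both directions. The gene tpm3 fell 2.83-fold, from 39515 ± 357 to 13984 ± 186 (SD, n = 3), with a log2 change of -1.50 (SE 0.05, limma adjusted p = 1.34e-12). Its paralogue tpm1 fell from 1048 ± 48.5 to 638 ± 33.0 (log2 change -0.71), and tpm4a rose from 5624 ± 386 to 7292 ± 120 (0.38). For TPM4 the log2 change was 0.18 and did not pass the test (limma adjusted p = 0.0872), and it passed without control replicate 3 (0.0300). The most abundant, tpma, had 244637 ± 18329 and 276842 ± 4899.9, a log2 change of 0.18 that did not pass the test either (limma adjusted p = 0.0886). It was -0.05 after quantile normalization, and it passed with DESeq2 (adjusted p = 0.00658) and without control replicate 1 (limma adjusted p = 0.0497). As a list of 4 members without tpma, tropomyosins gave a median of -0.27 and a camera adjusted p of 0.487, against 4.63e-04 with edgeR and 5.21e-07 with DESeq2. The gene tpm3 also belonged to the orthologues of mammalian transcripts reported to be spliced under QKI control, of which 7 of 19 rose and 6 fell (median -0.01, camera adjusted p = 0.952). There NDRG2 rose (0.80), while MYO18A (ENSDARG00000075752) fell (-0.58), as did RAI14 (-0.41).

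**Figure D1:**
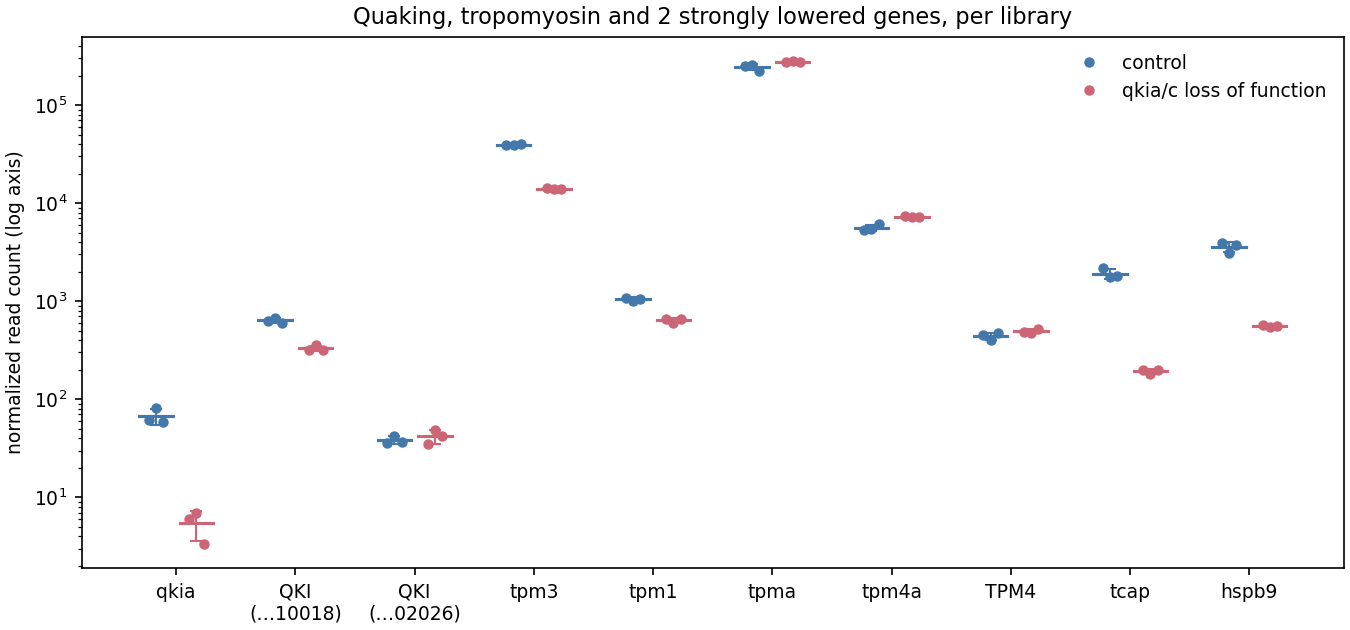
Normalized read counts on a log axis for the 3 quaking genes, 5 tropomyosin genes, tcap and hspb9 in the 6 libraries. Points are libraries, horizontal lines are group means and bars are SDs (n = 3). The loss of function libraries lie below all controls for qkia, the QKI gene ENSDARG00000010018, tpm3, tpm1, tcap and hspb9.

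Among named genes with a mean of at least 50, the 12 largest decreases included 4 genes of the sarcomere. The titin-binding Z-disc gene tcap fell 9.82-fold, from 1910 ± 215 to 193 ± 12 (SD, n = 3; log2 change -3.30, SE 0.08, limma adjusted p = 6.80e-14). The troponin T gene tnnt2e had a log2 change of -1.94, myoz3a, which encodes a calcineurin-binding Z-disc protein, -1.86, and the alpha-actinin gene actn2b -1.77. ANKRD1 (ENSDARG00000075263), whose mammalian counterpart responds to muscle stretch, fell by 1.83 on the log2 scale. A pair of small heat shock genes fell with them, hspb9 from 3576 ± 435 to 558 ± 10.8 (-2.67) and hspb9l (-1.91). The remaining 5 were the zinc finger transcription factors egr2a (-2.14) and EGR3 (-1.86), the homeobox gene EN2 (ENSDARG00000026599, -2.15), the lysozyme gene lyz (-2.07) and c6.1 (-1.87).

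Of the 12 largest increases, 6 were genes of red blood cells. They were the globin genes hbae4 (log2 change 2.59), HBE1 (ENSDARG00000087390, 2.35), hbae1.3 (2.34) and hbae1.1 (2.32), the anion exchanger SLC4A1 (ENSDARG00000012881, 2.53) and the erythroid transcription factor klf1 (2.33). The largest were drll.3, which rose 8.62-fold from 21.1 ± 7.30 to 184 ± 25 (SD, n = 3; 3.11), and ABHD8, from 26.5 ± 6.85 to 229 ± 11.2 (3.09). The liver-type fatty acid binding protein gene fabp10a (2.55), znfl2a (2.43), rell2 (2.36) and RFESD (ENSDARG00000058725, 2.32) made up the rest. Reads of globin genes with near-identical copies may be divided between them, so the values of single globin genes are uncertain.

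Genes were also examined in 29 lists fixed before the data were examined. The camera test with its preset correlation called 5 of them, 3 higher and 2 lower. With an estimated correlation camera called 0, none having an unadjusted p under 0.05, and fry, which does not compare a list with other genes, called 16. In that setting camera also uses only the 4 residual degrees of freedom, which by itself raises p. With the statistics of edgeR 7 lists were called and with those of DESeq2 8, and both added the quaking genes and the tropomyosins. Of the 10 ways to divide the 6 libraries into 3 and 3, 7 gave at least 5 called lists. Each split other than the real one keeps part of the group difference between its sides. This count therefore does not show how many lists chance alone would call.

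The list of primitive erythroid genes rose. Of 20 measured members, 19 rose, with a median log2 change of 2.02 (camera adjusted p = 1.75e-08; adjusted p = 0.547 with an estimated correlation). Adjusted over the list alone, 19 rose as well. The nuclear regulator hemgn had a log2 change of 2.30, carbonic anhydrase cahz 2.12, the first enzyme of heme synthesis alas2 2.17 and the zinc finger gene blf 1.38. The member that fell was the second gene named SLC4A1 (ENSDARG00000024560, -0.84). Named globin genes took up 0.0563% ± 0.0251 of all gene values in controls and 0.215% ± 0.00180 in loss of function (SD, n = 3), with controls ranging from 0.0312% to 0.0814%. In the same libraries, genes of the yolk syncytial layer, liver and gut gave 7 of 23 higher and 4 lower (median 0.11, camera adjusted p = 0.484), where fabp10a rose the most (2.55), apobb.1 (0.29) and apoeb (0.33; limma adjusted p = 0.0663 without the trend) rose, and FABP1 (ENSDARG00000019357) fell (-0.67). The hatching gland protease genes he1.3 and he1.1, looked at only after the values had been seen, had log2 changes of 1.53 and 1.73. For he1.1 there were only 7, 2 and 13 reads in controls and 20, 22 and 20 in loss of function, so its change is uncertain.

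Endothelial and leukocyte genes moved in both directions and did not pass the camera test. Of 20 endothelial genes, 5 rose and 7 fell (median 0.07, camera adjusted p = 0.874). Those that rose were LMO2 (1.35) and TAL1 (0.90), which are shared with blood progenitors, together with cdh5 (1.31), CLDN5 (ENSDARG00000014059, 0.62) and she (0.19), whereas tek fell (-0.69). Of 26 leukocyte genes, 10 fell and 5 rose (median -0.20, camera adjusted p = 0.415). The collagenase gene mmp13a fell from 38.4 ± 18.1 to 5.58 ± 1.99 (SD, n = 3; -2.53), and CORO1A (-0.82) and MMP9 (-0.66) also fell, while rac2, CXCR4 (ENSDARG00000057633), MYB, CEBPA and GRAP2 rose by log2 changes between 0.21 and 0.65.

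Of 15 slow muscle genes, 9 were lower, 1, TNNI1 (ENSDARG00000052708, 0.75), was higher and 5 did not pass the test, with a median log2 change of -0.30 (camera adjusted p = 0.0109; adjusted p = 0.547 with an estimated correlation). The ryanodine receptor gene RYR1 (ENSDARG00000011422), the calcium release channel, fell 1.92-fold (-0.94), the slow troponin T gene TNNT1 3.46-fold (-1.79), the troponin T gene tnnt2d 1.59-fold (-0.67) and the slow fiber transcription factor PROX1 1.52-fold (-0.60). The more abundant RYR1 copy (ENSDARG00000023797) had a log2 change of 0.22 and did not pass the test (limma adjusted p = 0.107). TNNT1 had means of only 43.8 in controls and 12.3 in loss of function. Among abundant members, myl10 fell (-0.23), and tnnt2c (-0.12), TNNC1 (-0.09) and MYOM1 (-0.01) did not pass the test. The slow myosin genes smyhc1, smyhc2 and smyhc3 were planned members but were not matched to a gene ID. Fast muscle contractile genes divided, with 11 of 28 lower and 5 higher (median 0.00, mean -0.10, camera adjusted p = 0.683). There myhz2, a fast myosin heavy chain, fell (-1.02), as did the parvalbumin gene pvalb4 (-0.57) and the troponin I gene TNNI2 (ENSDARG00000029069, -0.47). Its copy ENSDARG00000035958 rose (0.48), as did TNNI2 (ENSDARG00000029995, 0.63), myhz1.3 (0.43), ACTA1 (ENSDARG00000055618, 0.31) and MYL1 (ENSDARG00000014196, 0.20). Myosin heavy chain and troponin I genes have close copies, so their single values are uncertain.

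Genes for assembly of the Z-disc, M-band and thin filament also divided, with 9 of 41 lower and 10 higher (median 0.00, mean -0.17, camera adjusted p = 0.837). Besides tcap and actn2b, the filamin gene FLNC (ENSDARG00000018566) fell 2.25-fold (-1.17), whereas KLHL41 (ENSDARG00000006757) rose (0.46). The more abundant FLNC copy (ENSDARG00000018820) had a log2 change of 0.07 and did not pass the test (limma adjusted p = 0.387). In excitation-contraction coupling, 7 of 26 genes fell and 10 rose (median 0.08, mean -0.04, camera adjusted p = 0.952). The voltage sensor gene CACNA1S (ENSDARG00000029457) fell 2.01-fold (-1.01) and its partner CACNB1 1.54-fold (-0.63), and JPH1 (ENSDARG00000038826), which joins the plasma membrane to the sarcoplasmic reticulum, rose (0.50). The more abundant CACNA1S copy (ENSDARG00000042552) had a log2 change of 0.02 and did not pass the test (limma adjusted p = 0.830). Myogenic regulators and fusion genes gave 6 of 24 higher and 7 lower (median 0.04, camera adjusted p = 0.952). The fusion receptor gene jam2a rose 1.92-fold (0.94) and MEF2C (ENSDARG00000029764) rose (0.30), while PAX3 (ENSDARG00000010192, -0.47) and CDON (-0.35) fell.

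Chaperone and heat shock genes were higher as a list, with 17 of 30 higher and 3 lower (median 0.19, camera adjusted p = 0.00152; adjusted p = 0.547 with an estimated correlation). HSPA8 (ENSDARG00000037403) rose 2.48-fold (1.31), HSPB1 1.54-fold (0.62), the co-chaperone dnajb1b 1.53-fold (0.62) and the mitochondrial chaperonin HSPE1 1.40-fold (0.48). This HSPA8 copy had a mean of only 58.5 in controls. The other copy (ENSDARG00000068992), with a mean of 208468 in controls, had a log2 change of 0.19 and did not pass the test (limma adjusted p = 0.0551). The 3 members that fell were HSPH1 (-0.75), the muscle methyltransferase SMYD1 (ENSDARG00000009280, -0.57) and HSP90AB1 (-0.29). The small heat shock genes hspb9 (-2.67) and hspb9l (-1.91), which fell further, were not members of this list. Mitochondrial and energy genes gave 15 of 30 higher and 2 lower (median 0.19, camera adjusted p = 0.0146; adjusted p = 0.547 with an estimated correlation). ENO1 (ENSDARG00000022456, 0.54), ALDOA (ENSDARG00000034470, 0.49) and cycsb (0.43) rose. Both genes named PFKM, the muscle phosphofructokinase, fell (ENSDARG00000060797, -1.75; ENSDARG00000014179, -0.43). This list no longer passed the test after quantile normalization (camera adjusted p = 0.336) or without control replicate 3 (0.0715).

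Of 37 neural tube genes, 18 were lower, 1, SOX1 (ENSDARG00000008131, 0.26), was higher and 18 did not pass the test, with a median log2 change of -0.21 (camera adjusted p = 1.50e-04; adjusted p = 0.547 with an estimated correlation). The largest falls were those of SLC6A5 (-1.95) and CHAT (-1.01). PAX2 (ENSDARG00000028148) fell 1.64-fold (-0.72), the GABA synthesis gene GAD1 (ENSDARG00000027419) 1.44-fold (-0.52), the neuronal RNA-binding protein gene ELAVL3 1.43-fold (-0.51) and the Notch ligand gene dlb 1.33-fold (-0.41). Head, brain and eye genes gave 6 of 21 lower and 1 higher, DLX2 (ENSDARG00000079964, 0.26), with a median of -0.34 (camera adjusted p = 0.143). EN2, hoxb1a (-0.61), OTP (ENSDARG00000014201, -0.53) and PAX6 (-0.48) were among those that fell. Neural crest and pigment genes gave 9 of 23 lower (median -0.16, camera adjusted p = 0.160), among them TYRP1 (ENSDARG00000056151, -0.57), TFAP2E (-0.57), DCT (-0.43) and EDNRB (ENSDARG00000089334, -0.36).

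In the same libraries, Hox genes, whose paralogue number follows their order along the body axis, changed by position. In paralogue groups 1 to 4, 10 of 11 genes fell and 1, hoxa2b (0.20), rose, with a median log2 change of -0.42. In groups 5 to 8, 8 of 10 fell (median -0.35). In groups 9 to 13, 8 of 17 rose and 1, HOXC12 (-0.57), fell (median 0.09). The Hox genes were looked at after the lists had been tested.

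**Figure D2:**
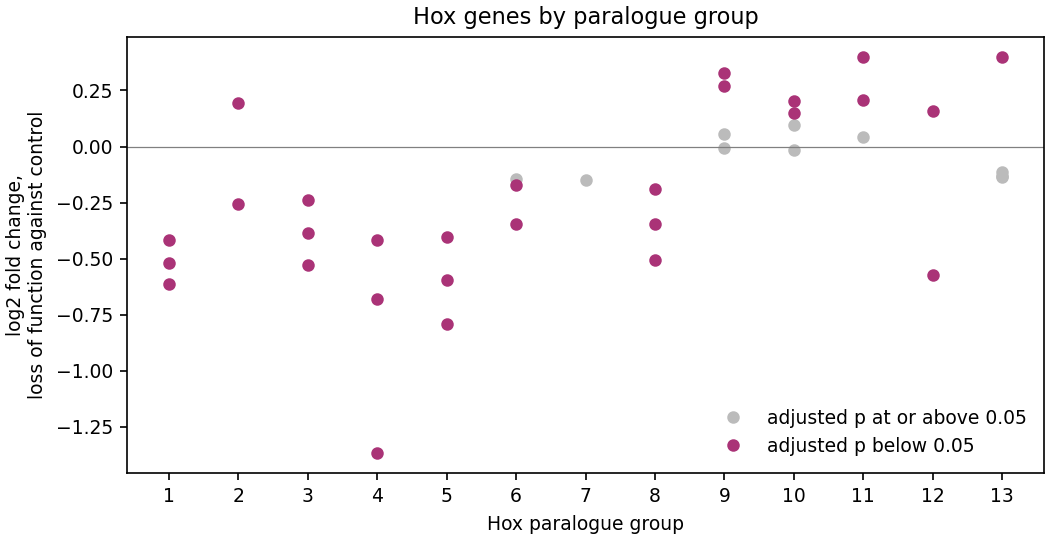
Log2 fold change of 38 Hox genes in loss of function against control, by paralogue group. Each point is a gene, colored by whether its limma adjusted p was below 0.05. Groups 1 to 4 have a median of -0.42 and groups 9 to 13 a median of 0.09.

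Genes of the notochord gave 14 of 25 higher and 5 lower (median 0.26, camera adjusted p = 0.160). The endoplasmic reticulum gene rcn3 rose 1.69-fold (0.76) and the collagen gene COL2A1 (ENSDARG00000069093) 1.37-fold (0.45). Those that fell were MATN3 (ENSDARG00000069245, -1.31), CCN2 (-0.86), epyc (-0.39), CCN1 (-0.23) and the other COL2A1 gene (ENSDARG00000011407, -0.17). In the Hedgehog and muscle pioneer list, 7 of 17 fell and 3 rose (median -0.17, camera adjusted p = 0.160). Besides EN2, OLIG2 fell (-0.41), while SHH (ENSDARG00000068567, 0.31) and both GLI2 genes (ENSDARG00000020884, 0.43; ENSDARG00000025641, 0.16) rose. Myotendinous junction and extracellular matrix genes gave 10 of 39 higher and 8 lower (median 0.00, mean -0.03, camera adjusted p = 0.791), with TGFBI (0.50), SPARC (0.31) and FN1 (ENSDARG00000019815, 0.33) higher and the other FN1 gene (ENSDARG00000006526, -0.78) and COL6A3 (-0.57) lower.

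Among splicing regulators, 14 of 39 fell and 9 rose (median -0.06, camera adjusted p = 0.415). PTBP2 fell 1.71-fold (-0.77), CELF3 (ENSDARG00000034668) 1.45-fold (-0.54), RBFOX1 1.36-fold (-0.45) and TRA2B 1.27-fold (-0.34). Among those that rose were MBNL3 (0.84) and MBNL1 (0.55), named after their values had been seen.

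In the unfolded protein and integrated stress response list, 10 of 30 rose and 8 fell (median 0.00, mean -0.06, camera adjusted p = 0.952). ATF3 fell 2.54-fold (-1.34), nupr1b 1.93-fold (-0.95) and CHAC1 1.65-fold (-0.72), and ASNS, asparagine synthetase, rose 1.58-fold (0.66). Of 14 interferon response genes, 1 rose, isg20 (0.77), and 4 fell, among them mxe (-0.73), SOCS3 (ENSDARG00000026611, -0.47) and SOCS3 (ENSDARG00000025428, -0.63), with a median of -0.24 (camera adjusted p = 0.236). The last of the genes named did not pass the test without control replicate 3 (-0.33, limma adjusted p = 0.0641), without loss of function replicate 2 (0.0666), with DESeq2 (adjusted p = 0.101) or with eBayes without the trend (limma adjusted p = 0.126).

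The remaining lists did not pass the camera test. Cell cycle genes gave 11 of 35 higher and 6 lower (median 0.04, camera adjusted p = 0.593), with AURKB (0.81), TYMS (0.42) and CDK2 (0.36) higher and bub1 lower (-0.39). Tailbud and somite clock genes gave 8 of 32 higher and 5 lower (median 0.03, camera adjusted p = 0.777). ALDH1A2 (0.59) and ripply1 (0.43) rose, and dlc (-0.66), HES6 (ENSDARG00000007097, -0.50), CYP26A1 (-0.32), her1 (-0.28) and her15.1 (-0.21) fell. Of 25 epidermal genes, 8 rose and 1, foxi3a (-0.72), fell (median 0.07, camera adjusted p = 0.160), and krt8 (0.46), agr1 (0.41), cldni (0.39) and krt17 (0.35) were among those that rose. Of 19 pronephros genes, 7 fell, with PAX2 and MECOM (-0.65) among them, and 3 rose, CDH17 (0.54), SLC20A1 (ENSDARG00000020114, 0.45) and AQP3 (0.36), with a median of -0.11 (camera adjusted p = 0.415). Of 9 heart genes, MYH6 (1.60), TNNT2 (2.30-fold), TNNI1 and SMYD1 (ENSDARG00000091253, 0.35) rose, and TBX20 (-0.78) and the other SMYD1 gene fell (median -0.05, mean 0.23, camera adjusted p = 0.855). MYH6, TNNT2 and TNNI1 had means of only 22.3, 14.1 and 20.3 in controls. The quaking genes as a list of 3 gave a camera adjusted p of 0.143, against 0.00202 with edgeR and 0.00753 with DESeq2.

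Adjusted over the list alone, the counts of higher and lower members were the same as over all genes in 14 of the 29 lists. In 14 of the others, 2 tropomyosins rose, 11 Z-disc genes, 9 excitation-contraction coupling genes, 19 neural tube genes, 6 notochord genes, 8 endothelial genes, 11 leukocyte genes, 8 pronephros genes and 9 stress response genes fell. By the same adjustment 18 chaperone genes and 9 yolk, liver and gut genes rose, 4 Hedgehog genes rose and 8 fell, 17 mitochondrial and energy genes rose and 4 fell, and in the head list 0 rose and 4 fell. The camera statistic pointed upward, against the sign of the mean, for excitation-contraction coupling, extracellular matrix and stress response genes, and against that of the median for heart genes. It pointed downward for Z-disc genes, whose median was 0.002 and mean -0.17.

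**Figure D3:**
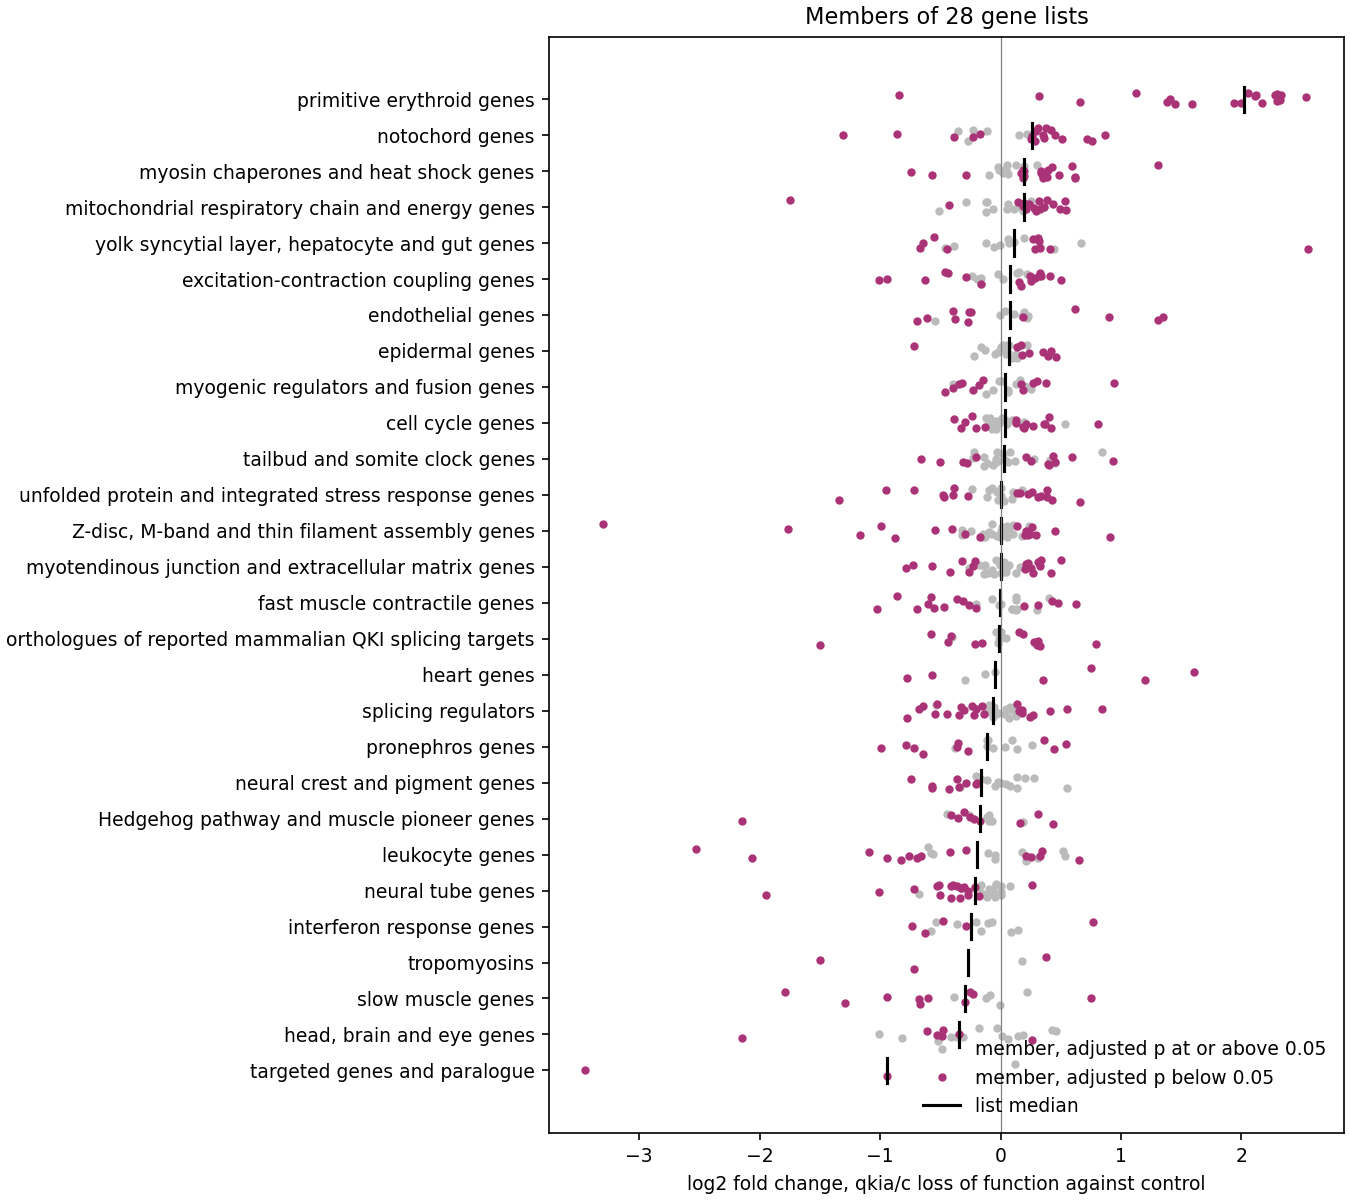
Log2 fold change, loss of function against control, of each measured member of 28 of the 29 gene lists, ordered by list median. Points are genes, colored by whether their limma adjusted p was below 0.05, and black bars are list medians. The primitive erythroid list stands at a median of 2.02, and every other list that passed the camera test has a median between -0.30 and 0.19.

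On the log2(value + 1) scale, some single exons had larger changes than any gene tested. Exon values are not paired with genes in the tables used here, so each exon was tested on its own and its change includes that of its gene. Of 109240 exons with a mean of at least 10, 12623 were higher and 7751 lower in loss of function trunks at a limma adjusted p under 0.05. On recovered reads, edgeR called 11498 and 9488. Exon ENSDARE00000776632 fell 60.6-fold, from 12301 ± 1023 to 202 ± 4.37 (SD, n = 3; log2 change -5.92, limma adjusted p = 3.11e-40), and ENSDARE00000916538 fell 55.7-fold, from 556 ± 47.9 to 9.24 ± 2.92 (-5.80). In the other direction, ENSDARE00000999695 rose 11.5-fold, from 9.39 ± 3.03 to 115 ± 11.6 (3.52), and ENSDARE00000866624 rose 10.3-fold, from 8.33 ± 3.44 to 92.0 ± 16.0 (3.37). The furthest change of a tested gene was that of pth1b, -4.47 (88.7 in controls and 3.10 in loss of function), and in the upward direction that of ENSDARG00000093754, 3.31 (0.294 and 11.3). The pseudocount shrinks the change of that gene, whose ratio of means exceeds those of the 2 exons that rose, so in this direction the order depends on the scale. Among exons that passed the test, had non-overlapping groups and a mean of at least 50, 7 lay below and 2 above these gene values. Without control replicate 2 the count of lower exons was 5142, and without loss of function replicate 1 that of higher exons was 8309.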

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

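The exon counts and all their alternatives were added after the data were seen, and the other alternatives were fixed before the data were examined. For genes, every alternative run gave a count within 1.5 times that reported, in each direction. Leaving out 1 library at a time gave 3112 to 4484 higher and 2965 to 3860 lower genes, 8309 to 13200 higher and 5142 to 6950 lower exons, and 5 lists each time. These were not always the same 5, as the mitochondrial and energy list did not pass without control replicate 3 (camera adjusted p = 0.0715). The lowest exon counts came without loss of function replicate 1 (8309) and without control replicate 2 (5142), and the reason was not tested. The log2 change of qkia stayed between -3.62 and -3.19 in these fits, that of QKI (ENSDARG00000010018) between -0.997 and -0.895, and that of QKI (ENSDARG00000002026) between 0.01 and 0.24.

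The number of called lists was 8 with DESeq2 statistics and 0 with an estimated correlation in camera, where no list had an unadjusted p under 0.05. The estimated correlation differs from list to list and widens the test of lists whose members vary together. That is not the whole reason, because p also rose where the estimated correlation was below the preset 0.01. In the head, brain and eye list it was -0.018, and the unadjusted camera p went from 0.0309 to 0.0773. With an estimated correlation, camera also refers its statistic to the 4 residual degrees of freedom. A preset correlation allows far more of them, so this by itself raises p. How much each part contributed was not tested. The change of tpma reversed to -0.045 with quantile normalization (limma adjusted p = 0.540), and it passed the test with DESeq2 (0.18, adjusted p = 0.00658) and without control replicate 1 (0.20, limma adjusted p = 0.0497). The cause was not tested. Of 2070 alternative values for the 130 named genes, 2061 kept their direction and side of the threshold, and the exceptions were those of tpma, TPM4, SOCS3 (ENSDARG00000025428) and apoeb.

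The replicate numbers are shared between the groups, but libraries with the same number did not deviate together (correlations of -0.07, 0.01 and -0.02), and only those numbered 2 matched each other best. With the replicate number as a block, 4055 genes were higher and 3759 lower, 12475 exons were higher and 8150 lower, and 5 lists were called. The log2 change of each of the 130 named genes kept its direction and side of the threshold there.

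Depth limited genes with few reads. With 3 to 7 qkia reads in the loss of function libraries, the residual level of that gene is known only roughly. The planned exon usage results were not run under any setting.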

Other observations

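The gene groups and tests in this part, the Hox test included, were chosen after the gene table had been seen, with the values of several Hox genes, except the counts over other splits.

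Of 30 measured immediate early genes, which cells switch on within minutes of a stimulus, 23 were lower in loss of function trunks, 1, klf2a (log2 change 0.24), was higher and 6 did not pass the test, with a median of -0.48. The group was assembled after egr2a and EGR3 had been seen among the largest decreases, and it was not tested as a list. FOS fell 3.08-fold, from 2295 ± 225 to 742 ± 15.7 (SD, n = 3; log2 change -1.62, limma adjusted p = 3.16e-11). The log2 change was -1.72 for egr1, -1.64 for FOSB, -1.76 for FOSL1 and -1.05 for ier2b, and JUNB fell 2.15-fold. ATF3, BTG2, CCN1, CCN2 and EGR2 in this group also stood in other lists. No reason for this pattern was tested.

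Transcripts encoded by the mitochondrial genome rose. Of 13, 12 were higher and MT-ATP6 had 0.21 (limma adjusted p = 0.0537), with a median of 0.43. MT-CO1, a subunit of cytochrome oxidase and the most abundant gene in all 6 libraries, rose 1.73-fold, from 687052 ± 36476 to 1186400 ± 49126 (SD, n = 3; 0.79, limma adjusted p = 2.30e-05). Together these genes took 6.14% ± 0.147 of all gene values in controls and 8.33% ± 0.213 in loss of function.

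The higher erythroid transcripts might come from tissue of the yolk syncytial layer left on the trunks, from blood or other cells near the yolk, from a larger share of red-cell RNA, or from more erythroid transcripts per red cell. Tissue of the yolk syncytial layer would bring its abundant transcripts along. Against it as the whole cause, the upper quartile of log2 changes of 11 list genes with a mean of at least 200 was 0.30, and that of all 23 members 0.32, below the lower quartile of the erythroid list at 1.40. This weighs only weakly. A fold from added tissue depends on the level already in the trunk, and members with a high mean show it least. Other rows go with material from near the yolk. They are fabp10a (2.55), a less abundant member of the same list, and the hatching gland genes he1.3 (1.53) and he1.1 (1.73, few reads). Hatching gland cells lie over the yolk. The gene fabp10a rose most of the 23 members, of which 7 rose and 4 fell, FABP1 (ENSDARG00000019357, -0.67) among the latter. Blood or other cells kept from there at dissection, the number of red cells, their transcript levels and the loss of quaking itself all stay open and were not tested.

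The lower neural tube transcripts could come from a dissection further towards the tail in loss of function embryos. A cut further towards the tail would lower Hox genes of groups 1 to 4 against groups 9 to 13. The difference of their medians was -0.51 (95% bootstrap interval over genes -0.76 to -0.33, 10000 draws), which goes with such a cut. Genes are not independent replicates, so the interval does not cover variation between embryos. Values of several Hox genes had been seen before this test was set, so it is not separate support. Not all rows go with such a cut. Within groups 9 to 13, the genes of groups 12 and 13 divided. There hoxd13a (0.40) and HOXD12 (0.16) rose and HOXC12 (-0.57) fell. The genes hoxa13b (-0.14), HOXB13 (-0.13) and HOXC13 (-0.12) did not pass the test. Tailbud and somite clock genes did not rise as a list (median 0.03, camera adjusted p = 0.777), and the hatching gland genes he1.3 (1.53) and he1.1 (1.73, few reads) rose. Dilution by other transcripts, a change in axial patterning or in the number of neurons after loss of quaking stay open and were not tested.

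Groups of 3 and 3 make 10 splits of the libraries, too few for a share under 0.05. Each of the other 9 splits mixes libraries of both groups, so the difference between the groups adds to the spread within each side. Few gene and exon calls were bound to follow there, so these counts cannot decide whether the real split arose by chance. The real split called 7935 genes and was the 1 split of 10 with as many. The highest of the other 9 called 0 with limma and 0 with edgeR, and 141 to 358 genes at an unadjusted limma p under 0.05, against 9351 in the real split. For exons the real split called 20374, again the 1 split of 10 with as many, and the highest other 0 with limma, with 2028 to 3673 exons at an unadjusted p under 0.05 against 33123. For lists the real split called 5, the highest other 9, and 7 of the 10 splits gave at least 5. Part of the group difference remains between the sides of each other split, so the list counts cannot decide this either.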
